A study of Homo sapiens with 9 samples.

How the data were processed

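Gene expression was measured by RNA sequencing in 9 libraries of neural cells derived from 201B7, an established human induced pluripotent stem cell line. The labels gave 3 libraries each to the compound TR065, the compound TR033 and the solvent DMSO, and a single batch label to all 9. The series' design text calls the treated material neural organoids, while the labels give neural cells. Dose, exposure time and culture age were not given in the sources used here, and no structure was given for either compound code. Nothing in these sources says whether replicates were separate cultures, so every p-value measures only the spread between these samples.

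Per the labels' protocols, total RNA was extracted with a miRNeasy kit and its quality was read on a Bioanalyzer. Per the same protocols, full-length cDNA was made and amplified with the SMART-Seq mRNA Kit, then tagmented and indexed with Nextera XT. Per the submitters' processing notes, sequencer output was converted with bcl2fastq and the genome build was GRCh38. The aligner, the quantifier, the annotation release and any use of strand were not given in the sources used here. The authors deposited 1 table of 61587 genes, of which 20006 were protein coding, with gene coordinates on GRCh38. Per the file headers, it held an estimated count for each gene and library. These deposited estimated counts were not normalized: 87.0% of them, and 69.5% of those above 0, were whole numbers, and the totals differed between libraries. Per the file headers, it also held TPM values, scaled by the authors to a sum of 1000000 in each library. The gene length given beside each gene in bases, another deposited quantity per the file headers, came from an annotation whose release was not named. No entry lacked a gene identifier. The 1385 genes with a repeated symbol were carried under their identifiers, so they could not match a gene list by symbol.

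The estimated counts were rounded to whole numbers. Total counts per library ranged from 15.49 to 24.22 M (1000000), and 3 counts, taken as the floor of detection, corresponded to 0.124 to 0.194 CPM (counts per 1000000 counts). This floor covers counting error only. Genes were kept by filterByExpr of edgeR 4.0.16, with a minimum count of 10 and a minimum total of 15, which left 19136 genes. TMM factors lay between 0.984 and 1.02, and the common biological coefficient of variation was 0.199. All 9 libraries entered 1 edgeR quasi-likelihood fit on the group alone, in R 4.3.3. The contrasts were TR065 against DMSO, TR033 against DMSO and TR065 against TR033, the last being the direct test of a difference between the compounds. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes kept were called. Log2 fold changes are given with standard errors (SE), and some with 95% intervals, both derived from the F statistic of the test. CPM is given with the SD over 3 libraries.

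Lists of genes were tested with camera of limma 3.58.1 at its preset correlation of 0.01, two-sided, on log2 CPM with a prior count of 2, adjusted over the lists of a comparison. Of 51 lists, 50 had at least 5 measured members. They covered neuronal structure and signalling, cell classes, growth, stress, metabolism and signalling pathways, with 1085 distinct genes, of which 972 were measured. Some genes stood in more than 1 list, such as SYT1 among both synaptic and pan-neuronal genes. The test was repeated with the correlation estimated from the data and with fry. Counts of called members were made over all genes and adjusted over the list alone. The lists, the comparisons, the tests, the rule for named genes and the other settings tried were fixed before the data were examined.

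By that rule, a comparison named the 5 rising and 5 falling called genes of largest change with a mean of at least 10 CPM in the higher group, separate groups and a regular symbol. It also named 3 members of smallest adjusted p from each of the 6 lists of smallest camera p with at least a pair of called members, and 10 panel genes whatever their values. The panel held STMN2, GAP43, DCX, MAP2, TUBB3, SOX2, MKI67, PTP4A1, PTP4A2 and PTP4A3. Called members of other lists, where they are named in the text, were chosen after their values were seen.

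The calls of both compounds against the shared DMSO libraries were compared with the overlap of independent lists and with 100 simulations of unchanged groups. In these, all libraries, the DMSO ones included, were drawn gene by gene from the same means. Each other setting changed a single choice, except that the DESeq2 Wald test also brought its own size factors and filtering: the scaling, the low-count filter, the test, the libraries in the fit, a replicate block, the threshold, a minimum fold of 1.2, or 1 library left out. DESeq2 1.42.0 served as the other count test. A limma-trend fit on log2(TPM + 1) was added after seeing the data, as was a test of annotated terms of 15 to 300 genes. Trends of the libraries on gene length and on transcript GC content were removed with lowess curves, with intervals from 2000 bootstrap draws.

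The tests were run on simulated data with known answers, drawn from the real means and library sizes with 200 genes changed. A further list of genes was shifted by less, and calls in it were not counted as false. Genes were drawn independently, so the false shares below do not cover a spread that genes have in common. For TR065 against DMSO (18589 genes), 33.3% of genes changed 1.5-fold, 62.8% of those changed 2-fold and 74.4% of those changed 4-fold were called, and 6.8% of the calls were false. For TR033 against DMSO (18600 genes) these shares were 32.1%, 59.5%, 74.4% and 6%, and for TR065 against TR033 (18596 genes) they were 30.8%, 43%, 78.9% and 5.1%. No library was a copy of another: squared differences between replicates, scaled for depth, were on average 8.46 to 15.7 times those of counting error. Reads, variants and single isoforms were not analysed here. Genes with near-identical copies, overlapping genes and antisense genes are uncertain, because the way shared reads were counted is not given in the sources used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.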

Results

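The series concerns small molecules found in a screen of human neurons for growth of neurites, the processes from which axons and dendrites form. Its title names a thienopyridone, but which code is that compound is not given in the sources used here. RNA was sequenced from neural cells of the 201B7 line in 3 groups of 3 libraries, treated with TR065, with TR033 or with the solvent DMSO. Total counts (M, 1000000) were 18.92, 24.22 and 18.59 M with TR065, 17.49, 19.07 and 18.26 M with TR033, and 19.01, 15.49 and 20.42 M with DMSO. DMSO libraries stood apart from all treated ones on the first principal component, which held 18.3% of the variance, at 36 to 46 against -29.1 to 0.6. Correlations between libraries were 0.9798 to 0.9874 within groups and 0.9751 to 0.9842 between groups, across genes, which are not independent replicates. All genes of the mitochondrial chromosome, ribosomal RNA included, took 2.43 ± 0.02% of counts with TR065, 2.90 ± 0.03% with TR033 and 2.61 ± 0.14% with DMSO (SD, n = 3). This set is wider than the mitochondrially encoded list tested below. Cytosolic ribosomal proteins took 1.85 ± 0.05%, 1.66 ± 0.07% and 1.92 ± 0.03%. DMSO replicate 1 stood apart in markers of mesenchymal cells, with a score of 1.09 against -0.50 and -0.59 in the other DMSO libraries, on the log2 scale relative to their mean.

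TR065 against DMSO asked which genes changed with this compound rather than with the solvent alone. Genes of cell division fell together: of 35 measured members of the proliferation list, 25 fell and 10 did not pass, with a median log2 change of -0.82. MKI67 (ENSG00000148773.14; chromosome 10, 128096659 to 128126423, GRCh38), a marker of cycling cells, stood at 41.3 ± 3.97 CPM with TR065 and 90.1 ± 8.09 CPM with DMSO (n = 3), a log2 change of -1.12 ± 0.12 (edgeR adjusted p = 2.6e-04). TOP2A, which untangles replicated DNA, changed by -0.99 ± 0.10, and PLK1, a mitotic kinase, by -1.09 ± 0.12. Adjusted over the list alone, 29 members fell. The camera test gave an adjusted p = 7.83e-27, and adjusted p = 0.0832 with an estimated correlation. The list of neural progenitors and radial glia, the dividing cells of the developing brain, was called downward too. Of 28 measured, 11 fell, 1 rose and 16 did not pass (18 and 1 adjusted over the list alone), with a median of -0.33 and a camera adjusted p = 2.56e-07 (adjusted p = 0.0832 with an estimated correlation). Examples were ASPM, a spindle protein of dividing progenitors (-1.11 ± 0.19), the receptor phosphatase gene PTPRZ1 (-0.83 ± 0.16) and VIM, the intermediate filament vimentin (-0.57 ± 0.08). SOX2, a core progenitor factor, had a log2 difference of -0.02 ± 0.07 (adjusted p = 0.929).

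The list of proneural and newborn-neuron factors, which act between division and maturity, was also called downward with TR065. Of 20 measured, 10 fell and 10 did not pass (17 fell and 1 rose adjusted over the list alone), with a median of -0.46 and a camera adjusted p = 2.46e-09 (adjusted p = 0.131 with an estimated correlation). HES6, a promoter of neuronal commitment (ENSG00000144485.11; chromosome 2, 238238267 to 238240662), changed by -0.81 ± 0.11, IGFBPL1 by -0.66 ± 0.09 and SOX4 by -0.48 ± 0.07. In the Notch pathway, which keeps progenitors from differentiating, 5 of 17 measured members fell (9 adjusted over the list alone; median -0.37; camera adjusted p = 1.47e-04, adjusted p = 0.126 with an estimated correlation). These were JAG1, HEY1, HES5, DLL3 and NOTCH3. Markers of excitatory cortical neurons fell in 7 of 20 cases (11 fell and 1 rose adjusted over the list alone; median -0.46; camera adjusted p = 1.65e-05, adjusted p = 0.0832 with an estimated correlation), among them NEUROD6 at -1.20 ± 0.27.

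Lists of metabolic and secretory genes were called upward with TR065, with smaller changes. In cholesterol synthesis, 12 of 25 measured genes rose, 1 fell and 12 did not pass (19 and 1 adjusted over the list alone), with a median of 0.34 and a camera adjusted p = 8.22e-11 (adjusted p = 0.0832 with an estimated correlation). The enzymes MSMO1, IDI1 and DHCR7 rose by 0.49 ± 0.06, 0.50 ± 0.07 and 0.51 ± 0.07, or 1.4-fold, 1.41-fold and 1.42-fold. Of 35 nuclear genes of the respiratory chain, 7 rose and 28 did not pass (22 rose and 1 fell adjusted over the list alone), with a median of 0.22 and a camera adjusted p = 2.67e-10 (adjusted p = 0.122 with an estimated correlation). Examples were ATP5F1B, UQCRC2 and NDUFA4 at 0.22 ± 0.04, 0.27 ± 0.05 and 0.30 ± 0.06. Of 19 chaperones and stress genes of the endoplasmic reticulum, 5 rose and 14 did not pass (10 rose adjusted over the list alone), with a median of 0.25 and a camera adjusted p = 3.92e-08 (adjusted p = 0.0832 with an estimated correlation). HERPUD1 rose by 0.55 ± 0.09, the transcription factor gene XBP1 by 0.38 ± 0.07 and PDIA4 by 0.30 ± 0.06.

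Other lists were called upward with TR065. In the integrated stress response 6 of 27 rose (10 adjusted over the list alone), including ASNS at 0.49 ± 0.09 (camera adjusted p = 4.94e-06, adjusted p = 0.183 with an estimated correlation). Among p53 targets 2 of 22 rose (4 adjusted over the list alone), CDKN1A, an inhibitor of the cell cycle, at 0.74 ± 0.07 and TIGAR (camera adjusted p = 9.03e-06, adjusted p = 0.191 with an estimated correlation). Of 19 targets of NRF2, the regulator of oxidative stress genes, the ferritin genes FTL and FTH1 and PIR rose (5 adjusted over the list alone; camera adjusted p = 1.37e-04, adjusted p = 0.0701 with an estimated correlation). In fatty acid synthesis FADS2, SCD, ACSL3 and FADS1 rose, 4 of 16 (5 adjusted over the list alone; camera adjusted p = 0.0068, adjusted p = 0.0893 with an estimated correlation).

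Lists of neuronal structure and signalling were called downward with TR065, most through few members. In axon guidance 11 of 34 fell (15 adjusted over the list alone), including the receptor gene ROBO3 at -2.09 ± 0.30 and SEMA5A at -1.53 ± 0.22, with a median of -0.28 and a camera adjusted p = 4.61e-06 (adjusted p = 0.0701 with an estimated correlation). Of 27 voltage-gated ion channel genes, 4 fell, among them CACNA2D1, CACNA2D3 and KCNH7 (5 adjusted over the list alone; median -0.41; camera adjusted p = 2.69e-04, adjusted p = 0.131 with an estimated correlation). Of 46 synaptic genes, SLC17A6, a glutamate transporter, fell alone (1 adjusted over the list alone; median -0.22; camera adjusted p = 0.00169, adjusted p = 0.41 with an estimated correlation). Of 25 pan-neuronal markers, UCHL1 rose and NRSN1 fell (1 and 8 adjusted over the list alone; median -0.21; camera adjusted p = 0.00207, adjusted p = 0.427 with an estimated correlation). Of 31 neurite-growth genes, STMN4, NRCAM, DCX and CNTN2 fell (7 fell and 1 rose adjusted over the list alone; median -0.12; camera adjusted p = 0.0068, adjusted p = 0.459 with an estimated correlation). That list was not called without DMSO replicate 2 (adjusted p = 0.117, median -0.07). DCX, a microtubule protein of migrating neurons, changed by -0.44 ± 0.07 (adjusted p = 0.00323). The differences of STMN2, GAP43, MAP2 and TUBB3 were -0.09 ± 0.11, -0.01 ± 0.11, -0.15 ± 0.06 and -0.04 ± 0.07, none called (adjusted p = 0.734, 0.977, 0.237 and 0.824). Among target and feedback genes of MAP kinase, SPRY2, ETV5 and PHLDA1 fell, 3 of 20 (5 adjusted over the list alone; median -0.42; camera adjusted p = 4.5e-05, adjusted p = 0.0701 with an estimated correlation). Among RNA-binding and splicing regulators RBFOX2 and SRSF2 fell, 2 of 25 (9 adjusted over the list alone; camera adjusted p = 2.03e-05, adjusted p = 0.0832 with an estimated correlation).

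A few lists called with TR065 lost the call when certain single libraries were left out. YAP and SRF targets (median -0.17; 1 of 26 fell, AMOTL2; 4 fell and 2 rose adjusted over the list alone) had a camera adjusted p = 0.0131 (adjusted p = 0.232 with an estimated correlation), which became 0.0541 without DMSO replicate 1 and 0.0522 without TR065 replicate 3. Neurotrophic factors and receptors (median -0.36; GFRA1 and NTRK3 fell, 2 of 16, and 3 adjusted over the list alone) had an adjusted p = 0.0456 (adjusted p = 0.153 with an estimated correlation), which became 0.1, 0.0699 and 0.104 without DMSO replicate 2, DMSO replicate 3 and TR065 replicate 2. Mesenchymal markers, of which 7 of 19 fell adjusted over the list alone, had a median of -0.86 and an adjusted p = 0.0456 (adjusted p = 0.459 with an estimated correlation). Without DMSO replicate 1 that median was -0.08 (adjusted p = 0.518), and without TR065 replicates 1 and 3 the adjusted p was 0.115 and 0.103. The other 28 lists were not called, with adjusted p from 0.0509 to 0.917. They included inhibitory neurons, midbrain and hindbrain neurons, tubulins, astrocytes, oligodendrocytes, choroid plexus and ciliated cells, muscle, endothelial, myeloid, neural crest and epithelial cells, immediate early genes, heat shock, glycolysis and hypoxia, mitochondrially encoded and ribosomal proteins, and Wnt, BMP, Hedgehog, aryl hydrocarbon receptor, retinoic acid, interferon, apoptosis, lysosome, AMPK, histone and PTP4A genes. In the lists of choroid plexus and ciliated cells, aryl hydrocarbon receptor and interferon genes the median and camera's direction were upward but the mean was below 0. The PTP4A list (12 measured) holds phosphatases that thienopyridones are known to inhibit, and their partners. Its members PTP4A1 (chromosome 6, 63521746 to 63583588) and MRS2 rose, PTP4A1 by 0.38 ± 0.07 (adjusted p = 0.00739), while PTP4A2 and PTP4A3 differed by 0.11 ± 0.07 and -0.03 ± 0.14 (adjusted p = 0.445 and 0.935).

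**Figure D1:**
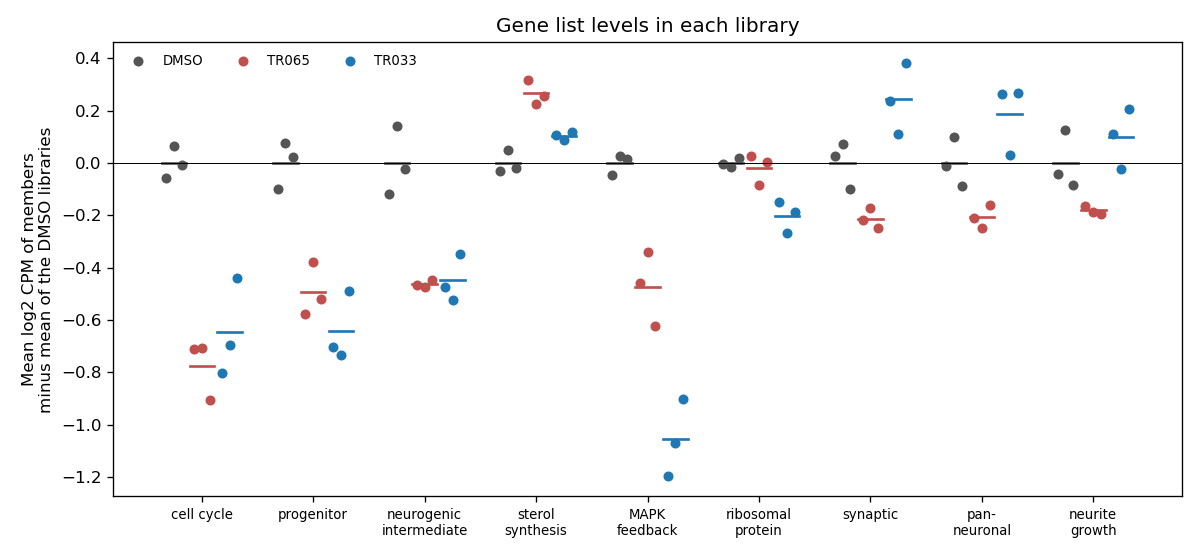
Mean log2 CPM of the members of 9 gene lists in each library, minus the mean of the DMSO libraries, with 1 point per library and a line at each group's mean. Proliferation, progenitor and neurogenic lists lie below DMSO on average with both compounds, while synaptic, pan-neuronal and neurite-growth lists lie below it with TR065 and above it on average with TR033.

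Among genes of at least 10 CPM in the higher group with groups apart, the largest called rise with TR065 was that of CCK, which encodes the neuropeptide cholecystokinin (ENSG00000187094.12; chromosome 3, 42257825 to 42266185). It stood at 42.65 ± 3.62 CPM against 7.74 ± 1.06 CPM with DMSO, 5.49-fold higher (log2 2.46 ± 0.16, adjusted p = 4.6e-06). PAPSS2, which makes the donor for sulfation, rose by 2.21 ± 0.31, PLS3, an actin-bundling protein, by 1.07 ± 0.11, and DEPTOR, an inhibitor of mTOR, by 0.96 ± 0.18. PGM5P4-AS1 rose by 1.25 ± 0.19, but it belongs to a family of near-identical loci and lies antisense to another gene, so its reads are uncertain. With the same limits, the largest falls were those of OLIG3 (-2.83 ± 0.60), a factor of dorsal and hindbrain progenitors, the ATP receptor gene P2RX3 (-2.66 ± 0.35), SLITRK6 (-2.36 ± 0.54), ROBO3 (-2.09 ± 0.30) and PRDM8 (-2.01 ± 0.26).

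In all, 767 of 19136 genes were called with TR065, 354 higher and 413 lower, with a median absolute log2 change of 0.55. Of these, 15 rose and 137 fell at least 2-fold. At an unadjusted p under 0.05 there were 3570 genes, and in 24.3% of all genes the groups did not overlap, where chance gives 10%. The count was 375, 290 and 329 without TR065 replicates 1, 2 and 3, and 249 without DMSO replicate 2. Of 30 called named genes, 24 kept the call without each library. The calls of OLIG3 (adjusted p = 0.0815 to 0.0864, without TR065 replicates 1 or 2 or DMSO replicate 2), DEPTOR (0.0541 to 0.0548, without TR065 replicate 2 or DMSO replicate 2), UQCRC2 (0.069, without TR065 replicate 2) and NDUFA4 (0.0501 to 0.0605, without TR065 replicates 1 or 2 or DMSO replicate 2) ended. So did those of PDIA4 and SLITRK6 without TR065 replicates 2 or 3 or DMSO replicates 1 or 2 (adjusted p = 0.0556 to 0.102 and 0.0577 to 0.104). None of the 22 called lists passed camera with an estimated correlation (0 called; 15 at an unadjusted p under 0.05), while fry called 21, not among them synaptic, pan-neuronal, neurite-growth and mesenchymal genes (fry adjusted p = 0.133, 0.135, 0.135 and 0.238).

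TR033 against DMSO asked the same of the second compound. The list of target and feedback genes of MAP kinase was called downward: of 20 measured, 9 fell and 11 did not pass (12 adjusted over the list alone), with a median of -0.85. ETV5 (ENSG00000244405.8; chromosome 3, 186046314 to 186110318), a transcription factor induced by growth factor signals, stood at 4.22 ± 1.75 CPM with TR033 and 30.9 ± 4.11 CPM with DMSO (log2 -2.87 ± 0.26, adjusted p = 1.29e-04). Its relatives ETV4 and ETV1 changed by -3.15 ± 0.40 and -2.43 ± 0.35, and SPRED2, an inhibitor of this pathway, by -1.27 ± 0.16. DUSP6, SPRED1, SPRY2, DUSP4 and PHLDA1 fell as well. The camera adjusted p was 1.51e-12, and this list alone passed with an estimated correlation (adjusted p = 0.0131).

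Proliferation and progenitor lists were called downward with TR033 too. Of 35 proliferation genes, 22 fell and 13 did not pass (33 adjusted over the list alone), with a median of -0.59 and a camera adjusted p = 3.39e-25 (adjusted p = 0.2 with an estimated correlation). The replication factors MCM7, GINS2 and MCM2 changed by -0.92 ± 0.09, -1.16 ± 0.15 and -0.81 ± 0.11, while the difference of MKI67, -0.40 ± 0.11, was not called (adjusted p = 0.0796). Of 28 progenitor genes, 10 fell, 1 rose and 17 did not pass (18 and 1 adjusted over the list alone), with a median of -0.53 and a camera adjusted p = 1.69e-10 (adjusted p = 0.155 with an estimated correlation). SFRP1, a secreted modulator of Wnt signals, changed by -1.97 ± 0.23, HES5, a Notch target, by -1.20 ± 0.14, and ID4 by -0.53 ± 0.08, while SOX2 differed by 0.12 ± 0.07 (adjusted p = 0.462). Of 20 proneural and newborn-neuron factors, 7 fell and 13 did not pass (12 adjusted over the list alone), with a median of -0.50 and a camera adjusted p = 1.11e-07 (adjusted p = 0.285 with an estimated correlation). HES6 changed by -1.15 ± 0.11, NEUROG2, a proneural factor, by -0.79 ± 0.10 and NHLH1 by -0.64 ± 0.08. In the Notch pathway HES5, HEY1, NOTCH1 and DLL3 fell, 4 of 17 (9 fell and 1 rose adjusted over the list alone; median -0.30; camera adjusted p = 2.22e-04, adjusted p = 0.285 with an estimated correlation).

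A few neuronal genes rose with TR033, in lists that camera called and fry did not (fry adjusted p = 0.0868 for synaptic, 0.0911 for pan-neuronal and 0.236 for neurite-growth genes). TR033 replicate 2 lay within the range of the DMSO libraries for pan-neuronal scores (0.029; -0.086 to 0.099), as did TR033 replicates 1 and 2 for neurite-growth scores (0.112 and -0.023; -0.085 to 0.127). Markers of excitatory neurons, axon guidance and ion channel genes were not called. Of 46 synaptic genes, 4 rose and 42 did not pass (6 rose adjusted over the list alone), with a median of 0.23 and a camera adjusted p = 3.06e-06 (adjusted p = 0.382 with an estimated correlation). SYT1, the calcium sensor of transmitter release (ENSG00000067715.14; chromosome 12, 78863993 to 79452008), rose 1.45-fold, by 0.53 ± 0.08 (adjusted p = 0.00178). VAMP2, of the release machinery, rose by 0.34 ± 0.08, and CPLX2 rose as well. Of 25 pan-neuronal markers, 7 rose and 18 did not pass (9 rose adjusted over the list alone), with a median of 0.25 and a camera adjusted p = 4.92e-05 (adjusted p = 0.452 with an estimated correlation). Of 31 neurite-growth genes, MAPT, MAP1B and GAP43 rose and STMN4 fell (10 and 2 adjusted over the list alone), with a median of 0.12 and a camera adjusted p = 0.0114 (adjusted p = 0.557 with an estimated correlation). That list was not called without TR033 replicate 3, DMSO replicate 1 or DMSO replicate 3 (adjusted p = 0.184, 0.0939 and 0.0832; medians 0.07, 0.12 and 0.06). GAP43, a protein of the growth cone, rose by 0.45 ± 0.11 (adjusted p = 0.0471) and TUBB3, the neuronal beta-tubulin, by 0.31 ± 0.07 (adjusted p = 0.023). STMN2, DCX and MAP2 differed by 0.32 ± 0.11, -0.08 ± 0.07 and 0.06 ± 0.06, none called (adjusted p = 0.147, 0.648 and 0.752).

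The list of ribosomal protein genes was called downward with TR033: of 34, 8 fell and 26 did not pass (24 adjusted over the list alone), with a median of -0.20 and a camera adjusted p = 1.62e-11 (adjusted p = 0.285 with an estimated correlation). RPS3, RPL10 and RPS6 changed by -0.31 ± 0.06, -0.31 ± 0.06 and -0.33 ± 0.07. Of 13 mitochondrially encoded genes, MT-ND1, MT-ND2, MT-ND4, MT-ND5 and MT-CYB rose (10 adjusted over the list alone), with a median of 0.27 and a camera adjusted p = 4.77e-05 (adjusted p = 0.382 with an estimated correlation). Scores of this list were uneven, at 0.397, 0.249 and 0.086 in TR033 replicates 1, 2 and 3, against -0.063 to 0.052 with DMSO. Genes of both lists share sequence with pseudogenes or nuclear copies, so their reads are uncertain. In the interferon response IFI44L, B2M, HLA-C and HLA-B fell, 4 of 23 (10 fell and 1 rose adjusted over the list alone; median -0.53; camera adjusted p = 0.00288, adjusted p = 0.382 with an estimated correlation), of which the HLA genes share reads with related genes. Interferon scores overlapped between libraries, at -0.25 in TR033 replicate 2 and -0.329 in DMSO replicate 3.

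Further lists were called with TR033 through few members. In cholesterol synthesis MVD, MSMO1 and TM7SF2 rose and 1 member fell (4 and 1 of 25 adjusted over the list alone; median 0.15; camera adjusted p = 0.00123, adjusted p = 0.382 with an estimated correlation). Among p53 targets CDKN1A, BBC3, TP53INP1 and PHLDA3 rose (5 of 22 adjusted over the list alone; median 0.13; camera adjusted p = 0.00166, adjusted p = 0.445 with an estimated correlation). Respiratory chain genes (35 measured, 35 did not pass) had a median of 0.07 and a camera adjusted p = 0.00305 (adjusted p = 0.469 with an estimated correlation), which became 0.0561 without TR033 replicate 1. Endothelial markers (5 measured, with a median of -1.12) had a camera adjusted p = 0.0304 (adjusted p = 0.285 with an estimated correlation), and 1 fell adjusted over the list alone. Without DMSO replicate 1 the camera adjusted p was 0.146 and the median -0.42. The mean endothelial score was lower still with TR065 (-1.48, against -1.101 with TR033), where the list was not called. RNA-binding and splicing regulators (median -0.12; PTBP1 fell, 1 of 25 adjusted over the list alone) had an adjusted p = 0.0348 (adjusted p = 0.382 with an estimated correlation). That became 0.0761, 0.0661, 0.0584 and 0.134 without TR033 replicates 2 and 3 and DMSO replicates 2 and 3. The other 34 lists were not called, with adjusted p from 0.0509 to 0.993. They were those not called with TR065, apart from ribosomal, mitochondrially encoded, interferon and endothelial genes, together with axon guidance, ion channels, excitatory neurons, chaperones of the endoplasmic reticulum, the integrated stress response, NRF2, fatty acid synthesis, YAP and SRF, neurotrophic and mesenchymal genes. The retinoic acid median was -0.30 while camera pointed upward; choroid plexus, tubulin, aryl hydrocarbon receptor and inhibitory neuron means were below 0 with medians above it, and the reverse held for histones. PTP4A1, PTP4A2 and PTP4A3 differed by 0.26 ± 0.07, 0.09 ± 0.07 and 0.07 ± 0.14, none called (adjusted p = 0.0556, 0.583 and 0.876).

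Among single genes, CCK had the largest rise named with TR033 as well, to 42.15 ± 6.96 CPM, 5.43-fold above DMSO (log2 2.44 ± 0.16, adjusted p = 5.11e-06), followed by PAPSS2 at 2.34 ± 0.31. CHRM3, a muscarinic acetylcholine receptor, rose by 1.59 ± 0.27, the kinase gene STK32B by 1.36 ± 0.27 and FEZF1-AS1 by 1.35 ± 0.20. The last is antisense to FEZF1, and since no use of strand is given, its reads cannot be told from those of its partner. Among genes of at least 10 CPM in the higher group with groups apart, OLIG3 fell furthest (-4.83 ± 0.70), followed, beside ETV5 and ETV1, by P2RX3 (-2.54 ± 0.35) and TKTL1 (-2.47 ± 0.41).

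With TR033, 588 genes were called, 260 higher and 328 lower, with a median absolute log2 change of 0.61; 33 rose and 105 fell at least 2-fold. At an unadjusted p under 0.05 there were 3020, and the groups did not overlap in 20.4% of all genes, where chance gives 10%. The count was 288 and 370 without TR033 replicates 1 and 2, and 311 and 332 without DMSO replicates 2 and 3. Of 29 called named genes, 23 kept the call without each library. Among the others, the calls of GAP43 (adjusted p = 0.0858 to 0.176), TUBB3 (0.0692 to 0.0976) and VAMP2 (0.0705 to 0.103) ended without TR033 replicates 1 or 3 or DMSO replicates 1 or 3. GAP43 and VAMP2 also lost the call in the fit of only the groups compared (adjusted p = 0.0891 and 0.0546). The calls of RPS6 (0.0504 to 0.0509, without TR033 replicate 2 or DMSO replicates 2 or 3) and STK32B (0.0504 to 0.0652, without TR033 replicate 2 or DMSO replicate 3) ended as well. Of the 16 called lists, 1 passed with an estimated correlation (7 at an unadjusted p under 0.05), and fry called 12, not among them the neuronal lists above, mitochondrially encoded, p53, interferon and respiratory chain genes (fry adjusted p = 0.055, 0.0942, 0.0942 and 0.0945 for the last 4).

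**Figure D2:**
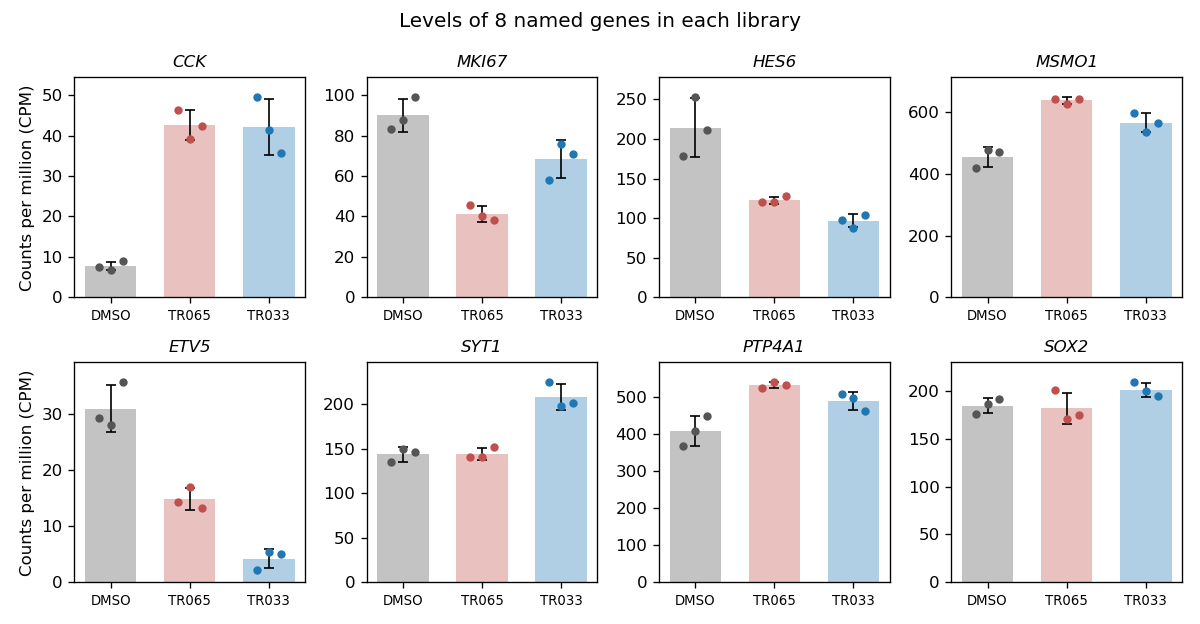
CPM of 8 named genes in each library; bars show the mean and error bars the SD of 3 libraries per group. CCK was higher and HES6 lower with both compounds, ETV5 was lowest with TR033, and SYT1 stood above DMSO with TR033 but not with TR065.

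TR065 against TR033 tested directly where the compounds differed. Dose and time of exposure are not given in the sources used here, so a difference may reflect either. Lists of neuronal genes were called lower with TR065 than with TR033. Of 46 synaptic genes, 6 fell and 40 did not pass (26 adjusted over the list alone), with a median difference of -0.43 and a camera adjusted p = 1.95e-15 (adjusted p = 0.127 with an estimated correlation). SYT1 stood at 144.5 ± 6.60 CPM with TR065 and 207.8 ± 14.7 CPM with TR033 (log2 -0.52 ± 0.07, adjusted p = 0.00804), and SNAP25, of the release machinery, differed by -0.40 ± 0.08. Of 25 pan-neuronal markers, 9 fell and 16 did not pass (17 adjusted over the list alone), with a median of -0.41 and a camera adjusted p = 8.25e-13 (adjusted p = 0.151 with an estimated correlation), among them NSG2 (-0.60 ± 0.08), the splicing factor gene CELF4 (-0.73 ± 0.11) and TUBB3 (-0.35 ± 0.07). Of 31 neurite-growth genes, the adhesion gene NRCAM (-0.73 ± 0.12), DCX (-0.36 ± 0.07) and the cannabinoid receptor gene CNR1 (-0.42 ± 0.10) fell (21 adjusted over the list alone), with a median of -0.29 and a camera adjusted p = 6.51e-10 (adjusted p = 0.233 with an estimated correlation). STMN2, GAP43 and MAP2 differed by -0.41 ± 0.11, -0.46 ± 0.11 and -0.20 ± 0.06, none called (adjusted p = 0.075, 0.0616 and 0.129).

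Lists of ion channel, guidance and excitatory genes were called in the same direction, through few members. Of 27 voltage-gated channel genes, SCN3B (-0.60 ± 0.13) and CACNA1E (-0.63 ± 0.14) fell (7 adjusted over the list alone), and SCN3A differed by -0.59 ± 0.14 without a call (adjusted p = 0.0587; list median -0.53; camera adjusted p = 2e-06, adjusted p = 0.127 with an estimated correlation). In axon guidance EPHA5 (-0.85 ± 0.14), PLXNA1 (-0.45 ± 0.08), PLXND1 (-1.11 ± 0.22) and UNC5A fell, 4 of 34 (10 adjusted over the list alone; median -0.24; camera adjusted p = 6.75e-06, adjusted p = 0.0829 with an estimated correlation). Among excitatory neuron markers RELN and TBR1 fell, 2 of 20 (6 adjusted over the list alone; median -0.34; camera adjusted p = 2.52e-04, adjusted p = 0.136 with an estimated correlation).

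Lists of folding, lipid and MAP kinase target genes were called higher with TR065, also through few members. Among 19 chaperones of the endoplasmic reticulum HERPUD1 (0.55 ± 0.09) and PDIA4 (0.33 ± 0.06) were called (8 adjusted over the list alone), and HSP90B1 differed by 0.23 ± 0.06 (adjusted p = 0.0515; list median 0.18; camera adjusted p = 5.87e-06, adjusted p = 0.127 with an estimated correlation). ETV5, ETV4, SPRED2 and ETV1 were higher, 4 of 20 MAP kinase targets (5 adjusted over the list alone; median 0.30; camera adjusted p = 2.1e-05, adjusted p = 0.0829 with an estimated correlation), ETV5 at 14.8 ± 1.90 against 4.22 ± 1.75 CPM (1.81 ± 0.26, adjusted p = 0.00783). In cholesterol synthesis IDI1 and FDFT1 were higher (12 of 25 adjusted over the list alone; median 0.17; camera adjusted p = 1.17e-05, adjusted p = 0.151 with an estimated correlation), and in fatty acid synthesis SCD, FADS2 and FADS1 (5 higher and 1 lower of 16 adjusted over the list alone; camera adjusted p = 0.00395, adjusted p = 0.127 with an estimated correlation). Heat shock genes HSP90AB1, HSP90AA1 and HSPD1 (10 of 18 adjusted over the list alone; camera adjusted p = 2.52e-04, adjusted p = 0.151 with an estimated correlation) and NRF2 targets FTL, PRDX1 and PIR (3 of 19 adjusted over the list alone; camera adjusted p = 0.00518, adjusted p = 0.127 with an estimated correlation) were higher. Of the interferon list 4 were higher, among them B2M, HLA-C and HLA-B (4 of 23 adjusted over the list alone; camera adjusted p = 6.5e-04, adjusted p = 0.271 with an estimated correlation).

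The ribosomal protein list was called higher with TR065 than with TR033 (RPLP0 called; 22 of 34 adjusted over the list alone; median 0.18; camera adjusted p = 1.33e-10, adjusted p = 0.233 with an estimated correlation), and the mitochondrially encoded list lower (MT-CYB and MT-CO3 called; 6 of 13 adjusted over the list alone; median -0.19; camera adjusted p = 0.00677, adjusted p = 0.555 with an estimated correlation, and 0.239 without TR033 replicate 1, where the median was -0.09). Respiratory chain genes had a median of 0.11, and 35 did not pass (camera adjusted p = 5.81e-05, adjusted p = 0.314 with an estimated correlation), and in the integrated stress response DDIT3 alone rose (1 of 27 adjusted over the list alone; camera adjusted p = 0.00413, adjusted p = 0.445 with an estimated correlation). Of 5 measured myeloid markers 2 were higher adjusted over the list alone (median 0.99; camera adjusted p = 0.00948, adjusted p = 0.136 with an estimated correlation), with scores of 0.53 to 0.83 in TR065 and -1.01 to -0.18 in TR033 libraries. Splicing regulators (RBFOX2 fell; 2 of 25 adjusted over the list alone; median -0.06) had an adjusted p = 0.04 (adjusted p = 0.339 with an estimated correlation), and 0.14, 0.0875, 0.0566 and 0.0621 without TR065 replicate 1 and TR033 replicates 1, 2 and 3. Proliferation genes (median -0.24) had an adjusted p = 0.0446 (adjusted p = 0.747 with an estimated correlation), and 0.451 and 0.748 without TR065 and TR033 replicate 3 (medians -0.15 and -0.06). In that list MKI67 (-0.73 ± 0.12, adjusted p = 0.0111) and TOP2A were lower with TR065, while 8 were lower and 2 higher adjusted over the list alone. An annotated set of 135 DNA replication genes, tested after the results were seen, was called in the opposite direction (135 did not pass; median 0.076, camera adjusted p = 0.0355, adjusted p = 0.251 with an estimated correlation). The other 30 lists were not called, with adjusted p from 0.0639 to 0.988. They were those not called with TR065, apart from ribosomal, mitochondrially encoded, heat shock, interferon and myeloid genes, together with proneural, progenitor, p53, Notch, YAP and SRF, neurotrophic and mesenchymal genes. Medians of choroid plexus, lysosome, AMPK and muscle genes were below 0 while camera pointed upward, and those of oligodendrocyte and apoptosis genes above 0 while it pointed downward. Means of glycolysis and endothelial genes were below 0 with medians above it.

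Of further single genes, the phospholipase gene PLA2G3 (1.26 ± 0.25), EHD4 (1.13 ± 0.23), ETV1 (1.73 ± 0.35) and the metallothionein gene MT1X (1.11 ± 0.26, adjusted p = 0.04999), which has close relatives, were higher with TR065. PLXND1, PCDH17 (-1.11 ± 0.25), CES4A (-1.08 ± 0.21), NDST3 (-1.03 ± 0.19) and the pacemaker channel gene HCN4 (-0.99 ± 0.21) were lower. Compounds were not told apart in CCK, with a difference of 0.02 and a 95% interval of -0.29 to 0.33, nor in PAPSS2 (-0.75 to 0.47) or P2RX3 (-0.88 to 0.63). The same held for PTP4A1 (0.12; -0.02 to 0.27), PTP4A2 (0.02; -0.13 to 0.16), PTP4A3 (-0.10; -0.41 to 0.20) and SOX2 (-0.14; -0.30 to 0.01), with adjusted p = 0.437, 0.95, 0.812 and 0.389 for these last genes.

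In all, 293 genes were called between the compounds, 154 higher with TR065 and 139 higher with TR033, with a median absolute log2 difference of 0.48 and 34 of at least 2-fold. At an unadjusted p under 0.05 there were 2883, and the groups did not overlap in 20.2% of all genes, where chance gives 10%. This comparison rested on single libraries more than those against DMSO: the count was 169, 18 and 11 without TR065 replicates 1, 2 and 3, and 37 and 21 without TR033 replicates 1 and 3. Each of the 26 called named genes lost the call without at least 1 library: 12, 2 and 2 kept it without TR065 replicates 1, 2 and 3, and 8, 18 and 3 without TR033 replicates 1, 2 and 3 (adjusted p up to 0.212). ETV5 and SYT1 lost it only without TR065 replicate 2 (adjusted p = 0.0516 and 0.052) and NSG2 only without TR065 replicate 3 (0.0501). MT1X also lost it with DESeq2 size factors. None of the 20 called lists passed with an estimated correlation (0 called; 12 at an unadjusted p under 0.05), while fry called 16, not among them interferon, integrated stress response, mitochondrially encoded and proliferation genes (fry adjusted p = 0.0902, 0.147, 0.176 and 0.442).

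Both comparisons against DMSO shared calls. In total, 228 genes were called in the same direction with both compounds, 78 higher and 150 lower. Independent lists of these sizes would share 4.81 and 7.08. Simulated unchanged groups against shared simulated DMSO libraries had 0.02 in common on average and 1 at most. Genes were drawn independently there, so a deviation that many genes of the real DMSO libraries share is not covered. They included CCK, PAPSS2, CDKN1A and UCHL1 among those that rose, and OLIG3, P2RX3, ROBO3, HES6, VIM and NEUROD1 among those that fell, some of them chosen after their values were seen. SCD, which makes monounsaturated fatty acids, was the 1 gene called in opposite directions, at 0.26 ± 0.06 with TR065 and -0.27 ± 0.06 with TR033 (direct difference 0.53, adjusted p = 0.00165). Log2 changes correlated at 0.55 across genes, against 0.50 on average in simulations (0.47 to 0.53), and their covariance was 0.191 against 0.0843 (0.0766 to 0.0922), a difference of 0.107. The 3 DMSO libraries are too few to be split, so part of the excess may come from the shared controls. Of 538 genes called with TR065 alone, 92 differed between the compounds in the direct test, as did 74 of 359 called with TR033 alone. The shared count was 124, 116 and 136 without TR065 replicates 1, 2 and 3, 131 and 151 without TR033 replicates 1 and 2, and 90 and 143 without DMSO replicates 2 and 3.

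**Figure D3:**
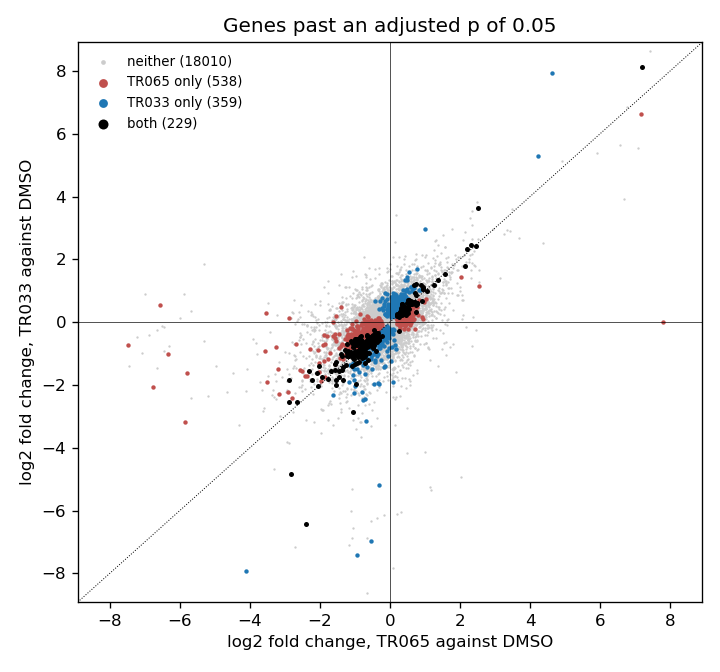
Log2 fold change of each of 19136 genes with TR065 (horizontal) and TR033 (vertical) against the same DMSO libraries, by the comparison in which it was called. The 229 genes called in both changed in the same direction with both compounds apart from SCD, though some by unlike amounts.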

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

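The test of the share of neurons and that of the share of dividing progenitors were chosen only after the results they bear on were seen. Groups of 3 libraries were too small to be tested for outlying libraries. Changes against DMSO differed between the compounds in lists of neuronal genes, by the direct test of TR065 against TR033. Synaptic genes had medians of -0.223 with TR065 and 0.231 with TR033 (direct median -0.426; camera adjusted p = 1.95e-15, adjusted p = 0.127 with an estimated correlation). Pan-neuronal markers had medians of -0.21 and 0.248 (direct -0.407; adjusted p = 8.25e-13, adjusted p = 0.151 with an estimated correlation). Neurite-growth genes had medians of -0.123 and 0.124 (direct -0.287; adjusted p = 6.51e-10, adjusted p = 0.233 with an estimated correlation). By fry these lists were called between the compounds but with neither compound against DMSO. Neurite-growth medians against DMSO lost their calls without DMSO replicate 2 with TR065 (adjusted p = 0.117), and without TR033 replicate 3, DMSO replicate 1 or DMSO replicate 3 with TR033 (adjusted p = 0.184, 0.0939 and 0.0832).

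Over the 99 genes of these neuronal lists, the median difference between the compounds was -0.355. The tests argued against gene length or GC content as the whole cause: 95.6% of the median was kept after the trend on length was removed (-0.34) and 97.8% after that on GC content (-0.348). A lower share of neurons in the TR065 libraries would raise markers of other cell classes alike. Of other cell classes with at least 10 measured members, the test took the progenitor, astrocyte, choroid plexus and mesenchymal lists. Their medians were 0.108, 0.094, -0.079 and -0.181 (interval of the last -0.634 to -0.07), but libraries of the groups overlapped in each. The neural crest list, with 12 measured members, was not in that test. Its mean score was -0.79 with TR065 and -0.514 with TR033, with libraries overlapping too. The list of 5 measured myeloid markers was called higher with TR065 by camera (median 0.991, and adjusted p = 0.136 with an estimated correlation), with libraries of the groups apart. Scores of 8 epithelial markers, a list not called, were apart the other way, at -0.521 to -0.387 with TR065 and -0.329 to 0.169 with TR033. Mean scores of oligodendrocyte, endothelial and muscle lists were also lower with TR065 (-0.403, -1.48 and -0.253) than with TR033 (-0.218, -1.101 and -0.189), with libraries overlapping. TTR stood at 18260 ± 2675 TPM with TR065 against 12840 ± 3079 TPM with TR033, not called. These values do not exclude the explanation, and a lower share of neurons and lower expression per neuron cannot be told apart. Both stay open, as does an untested difference in dose or time.

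The proliferation list was called lower with both compounds than with DMSO by camera at its preset correlation. With an estimated correlation the adjusted p was 0.0832 with TR065 and 0.2 with TR033. The trend on length, once removed, left 98.2% of the median, that on GC content left 101.3%, and leaving out 1 DMSO library left at least 92.4%, so none of these was the whole cause. A lower share of dividing progenitors and slower division of the same cells both stay open. The progenitor list shares no member with the proliferation list, so its medians, -0.333 with TR065 and -0.525 with TR033, repeat the result reported above and test neither.

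The ribosomal protein list was called lower and the mitochondrially encoded list higher with TR033 than with DMSO, by camera at its preset correlation. With an estimated correlation the adjusted p was 0.285 and 0.382, and fry did not call the mitochondrial list (fry adjusted p = 0.055). Of the ribosomal median, 109.1% was kept without the trend on length and 94% without that on GC content, and of the mitochondrial median 87.6% and 104.9%. These trends were therefore not the whole cause. Reads shared with pseudogenes or nuclear copies were not tested, and no biological explanation was tested.

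Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05, and in each comparison 1 of them, the real one, gave as many calls. By edgeR, 767, 588 and 293 genes were called for TR065 against DMSO, TR033 against DMSO and TR065 against TR033, and the highest other split gave 0 in each. At an unadjusted p under 0.05 the real splits gave 3570, 3020 and 2883 genes and the highest others 1082, 1100 and 1073. Gene lists called numbered 22, 16 and 20 against 13, 12 and 16 in the highest other splits. The 228 genes called in the same direction with both compounds were compared with splits of the 9 libraries. Of 100 splits (of 840 distinct), 1, the real one, gave as many, and the highest other gave 72. Other splits gave counts above 0 only where all DMSO libraries stayed together as the controls. The treated groups of those splits mixed TR065 with TR033 libraries, between which 293 genes were called, so lower counts there were partly built in. The real count stood above those of all other splits drawn, but a chance deviation shared by the DMSO libraries was not excluded.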

How the results depend on the processing

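The limma-trend fit on log2(TPM + 1) was chosen only after the data were seen. Counts are given for TR065 against DMSO, TR033 against DMSO, TR065 against TR033 and, where run, the shared response (main values 767, 588, 293 and 228). Without a low-count filter, which tests more genes, they were 1554, 1215, 997 and 538, and with the DESeq2 Wald test, on its own size factors and filtering, 1663, 1204, 1066 and 520. With an adjusted p threshold of 0.01 they were 191, 182, 19 and 63, and with a minimum fold of 1.2 (glmTreat) 141, 140 and 2, both stricter by construction. Limma-trend on TPM gave 453, 348 and 101, of which 28.3%, 34.5% and 31.7% were higher (46.2%, 44.2% and 52.6% in the main counts). A replicate block gave 600, 478, 156 and 179, but the numbers do not pair the libraries: 0 of 9 same-number pairs correlated over 0.1 (-0.046 to 0.055). DESeq2 size factors (755, 584, 296 and 227), voom (890, 642 and 382) and fits of only the groups compared (871, 426 and 355) stayed within 1.5 times. Leaving out 1 library at a time, which leaves fewer samples, gave 249 to 626, 288 to 444, 11 to 233 and 90 to 219. Lists called (22, 16 and 20) became 0, 1 and 0 with camera at an estimated correlation (15, 7 and 12 at an unadjusted p under 0.05), 21, 12 and 16 with fry, 21, 15 and 18 with the block, 21, 16 and 20 with size factors, and 21 to 23, 15 to 19 and 18 to 22 without 1 library. Of 85 called named gene results, 47 kept the call without each library and 38 lost it at least once, and of 58 called list results 47 kept it; no call turned direction in any setting run (0 of each). Of called named genes (30, 29 and 26), 12, 8 and 26 lost the call with the minimum fold and 6, 3 and 17 on TPM; 2 with TR033 lost it in the fit of only the groups compared, 2 with TR033 and 10 between the compounds with the block, and 1 between the compounds with size factors. Fry ended 4, 7 and 4 list calls, the block 2, 1 and 2, and size factors 1 with TR065 (mesenchymal). Where construction does not show it, the cause was not tested. Depth was 15.49 to 24.22 M counts. A pseudocount and a filter on low values, meant for a file without counts, were not run, since counts were deposited.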

Other observations

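Tests of annotated terms were chosen only after the results were seen. Of 2730 terms, camera called 411, 239 and 537 for TR065 against DMSO, TR033 against DMSO and TR065 against TR033, and 0 with an estimated correlation. Transport from the endoplasmic reticulum to the Golgi (108 genes) was called with TR065 (15 rose and 1 fell, median 0.187, adjusted p = 5.35e-09, adjusted p = 0.147 with an estimated correlation) and upward between the compounds (10 rose and 1 fell, median 0.139, adjusted p = 7.14e-07, adjusted p = 0.162 with an estimated correlation), but not called with TR033 (adjusted p = 0.419). A term of 49 genes, 42 of them proteasome subunits, was called likewise: 6 rose with TR065 (median 0.191, adjusted p = 3.19e-10, adjusted p = 0.0822 with an estimated correlation), and the adjusted p was 0.261 with TR033 and 4.58e-08 between the compounds (adjusted p = 0.0795 with an estimated correlation). The anterior-posterior patterning term (68 genes) was called downward with TR065 (9 fell, adjusted p = 6.78e-06, adjusted p = 0.129 with an estimated correlation) and TR033 (9 fell and 1 rose, adjusted p = 5.83e-04, adjusted p = 0.301 with an estimated correlation), with an adjusted p = 0.562 between them. The DNA replication term (135 genes) was called downward with TR065 (16 fell, median -0.102, adjusted p = 0.0017, adjusted p = 0.187 with an estimated correlation) and TR033 (25 fell, median -0.177, adjusted p = 4.42e-08, adjusted p = 0.236 with an estimated correlation), while between the compounds camera called the term upward although 135 did not pass (median 0.076, adjusted p = 0.0355, adjusted p = 0.251 with an estimated correlation). The ribosomal RNA processing term (155 genes) was called upward with TR065 (3 rose and 1 fell, median 0.07, adjusted p = 0.0313, adjusted p = 0.14 with an estimated correlation), downward with TR033 (5 fell, median -0.092, adjusted p = 0.0052, adjusted p = 0.236 with an estimated correlation) and upward between the compounds (4 rose, median 0.159, adjusted p = 1.15e-09, adjusted p = 0.0795 with an estimated correlation). Some terms overlap the lists above, so their calls are not separate results. HES6, HES5, HEY1 and SFRP1 of the patterning term stood in the proneural, Notch or progenitor lists. MCM7, GINS2 and MCM2 of the replication term stood in the proliferation list. RPS6, RPL5 and RPL7, which fell with TR033 in the ribosomal RNA processing term, are ribosomal protein genes.

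Genes chosen after their values were seen included regional factors of the developing brain that were lower with both compounds. HOXB2 changed by -1.78 ± 0.41 with TR065 and -1.82 ± 0.41 with TR033 and HOXB3 by -2.06 ± 0.51 and -2.03 ± 0.51. ATOH1 stood at 6.89 CPM with DMSO, 1.31 CPM with TR065 and 0.0759 CPM, below the 3-count floor of each library, with TR033. TTR, the main transcript of choroid plexus, rose with TR065 (0.67 ± 0.13, adjusted p = 0.0129) and stood at 18260 ± 2675 TPM, against 12840 ± 3079 TPM with TR033 and 11900 ± 1583 TPM with DMSO.

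DMSO replicate 1 also stood apart in markers of other cells: its epithelial score was 0.888 (-0.416 and -0.472 in the other DMSO libraries) and its endothelial score 0.634 (-0.216 and -0.417). COL1A1 stood at 28.97 ± 39.1 TPM with DMSO.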
